A study of Homo sapiens with 4 samples.

How the data were processed

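Single cells from the media of 4 human aortic segments (root, ascending aorta, arch and descending aorta) were profiled by droplet RNA sequencing of transcript 3' ends, with 1 library per segment. Per the labels' protocols, the tissue was digested with enzymes and single, viable cells negative for CD45 (a marker of blood leukocytes) and CD235a (a marker of red cells) were sorted before capture. The deposited values were raw UMI counts, that is, whole-number counts of distinct molecules per gene and cell, made by the authors with Cell Ranger 6.1.2, per the file headers. The reference was GRCh38 and Seurat 4.3 was among the tools named, per the submitters' processing notes. The gene annotation and the thresholds of the submitters' cell filter were not given in the sources used here. Each library held 36601 genes. The labels do not say whether the segments came from the same donor, so segment and donor may be confounded, and with 1 library per segment no test between segments was possible.

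Cells were filtered again from the deposited barcodes. The labels give the number of cells left by the submitters' filter, so 280 combinations of a minimum and maximum number of genes and a maximum percentage of mitochondrial UMIs were compared with those numbers, and the closest was used: at least 1000 and at most 5000 genes and at most 15% mitochondrial UMIs. It kept 1988 root, 946 ascending, 601 arch and 346 descending cells, against 1971, 943, 593 and 344 in the labels. Scrublet scores, computed within scanpy, ranked cells as possible doublets in each library, and the highest-scoring cells were removed at 0.8% per 1000 barcodes, which took out 62 cells (1.60% of those kept by the filter).

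The cells of all libraries were clustered together without integration: counts were scaled to 10000 per cell and log-transformed, 2000 variable genes gave 30 principal components, and Leiden clustering at resolution 0.5 on a graph of 15 neighbours weighted by shared neighbours gave 16 clusters. A cluster was called "X-like" when it had at least 3 detected markers of a class and no more markers of another class than of its own among its 10 leading genes. A marker counted as detected at 20 CPM and at least 2 times the median of the other clusters. A cluster of low median UMI count with no own marker among its leading genes would also have been left unnamed. The markers of 16 classes had been fixed before the data were examined. Clusters that failed were left unnamed and their share is given.

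Raw UMIs were then summed over the smooth muscle cell-like (SMC-like) cells of each library and expressed as CPM, in which every sum is scaled to the same total. The same was done for fibroblast-like cells, the other class with at least 50 cells in every library. A gene's log2 value in a segment compared CPM plus 2 with the geometric mean of the other 3 segments, and genes with 10 CPM and 10 UMIs in any segment counted as measured. For 26 gene lists and the 16 marker lists with at least 3 measured members, the median log2 value was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Those percentiles describe these libraries. Intervals of medians came from 200 Poisson resamplings of the counts. Single sums have exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95% and all covering counting error only. Depth ranged from 392066 UMIs in the descending SMC-like sum to 1630855 in the root sum, so that the floor of 3 UMIs per library corresponded to 7.65 CPM in the former and 1.84 CPM in the latter.

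Genes were named by a rule fixed before the data were examined, leaving out mitochondrial, ribosomal protein, sex-linked marker and clone-named genes. High in a segment were the 12 genes with the largest ratio to the next highest segment among those with 50 UMIs and 20 CPM there. Low were the 12 with the largest ratio of the next lowest segment to it, given 20 UMIs and 20 CPM in each of the other 3. Along the vessel, the 10 with the largest ratio between the ends were taken in each direction among genes ordered along the 4 segments with 50 CPM in any of them. In fibroblast-like cells the 6 highest were named per segment, and in each list the 2 most abundant members and the 2 with the largest log2 values; measured HOX genes were all named. Some genes picked by these rules are not reported here. A count of 0 entered a ratio as 3 UMIs. The ratios that counting noise alone would give were drawn 50 times from 1 shared composition. Gene coordinates are those of GENCODE 29 on GRCh38, matched by the gene identifiers of the files for 145 of 145 genes looked up.

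The ranking and list steps were tested on simulated data drawn with counting noise only from the real sums over 36601 genes. In them 200 genes with at least 50 CPM in the pooled class were raised in the descending sum. Recovery of named genes between 20 and 50 CPM, or in other segments, was therefore not tested. In the SMC-like simulation, 99 of 100 genes changed 4-fold were among the top 100 and 75 of 100 genes changed 2-fold among the top 200; the ratio intervals held the true value for 88.0% of the former and 90.7% of the latter, below the nominal 95%. In the fibroblast-like simulation these numbers were 100 and 98, with intervals holding the true value for 92.0% and 95.0%. Of 100 unchanged lists, 2% and 4% fell outside the middle 95% of matched lists in the respective classes. Alternatives covered the cell filter, doublet removal, clustering resolution, scaling, weighting of cells, thinning to 2000 UMIs per cell, pseudocount, minimum expression, the comparison segments and the naming minimums. A minimum of 1000 genes had been listed as an alternative and was the filter already in use. Restricting the SMC-like class to 1 of its 2 clusters, and adding an unnamed cluster to it, were alternatives chosen after seeing the data, as were those for the shares of other classes. Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used. Classes with fewer cells were described by their shares and, for endothelial-like and pericyte-like cells, by the levels of some regulators.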

Results

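The data set comprised 4 libraries of sorted cells from the human aortic media, 1 each from the root, the ascending aorta, the arch and the descending aorta. The libraries held 2692, 1394, 1157 and 640 barcodes with 17749786, 6856097, 5663212 and 3709401 UMIs. After filtering and doublet removal, 1945 root, 935 ascending, 595 arch and 344 descending cells were analysed. They had medians of 7499, 5266, 6183 and 7922 UMIs per cell. Because each segment was represented by 1 library, differences have no replicate check and values are given without a test. All intervals are 95% intervals of counting error only. The comparisons ask how the cell classes, and above all the smooth muscle cells that build the media, differ between segments along the vessel.

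Fibroblast-like cells, which carried DCN, LUM and PDGFRA, made up most of the root and descending libraries, whereas endothelial-like cells were more frequent in the ascending library than in the others. Fibroblast-like cells were 70.2% of root cells (68.1 to 72.3%) and 59.0% of descending cells (53.6 to 64.3%). They were 10.2% in the ascending aorta (8.30 to 12.3%; 17.1% with at most 5% mitochondrial UMIs) and 21.5% in the arch (18.3 to 25%). Endothelial-like cells reached 33.8% in the ascending library (30.8 to 36.9%), 15% in the arch, 8.72% in the descending and 5.76% in the root library. In the ascending library this share was 54.1% with at most 5% mitochondrial UMIs. With no doublets removed, it was 2.21%, 16.6%, 4.83% and 4.05% from root to descending, and 45.9% of ascending cells were without a class name. SMC-like cells, with MYH11, ACTA2 and CNN1, held a minor share in each segment, lowest in the root. It was 12.4% in the root (11 to 14%), 17.0% in the ascending aorta (14.7 to 19.6%), 16.3% in the arch (13.4 to 19.5%) and 17.2% in the descending aorta (13.3 to 21.6%). Pericyte-like cells, with RGS5 and KCNJ8, ranged from 5.81% in the descending to 9.75% in the arch library, but at clustering resolution 1.0 they were 8.53%, 21.6%, 17.6% and 11.3% from root to descending. With at most 5% mitochondrial UMIs they were 0.213% in the root, 17.1% in the ascending aorta and 17.5% in the arch.

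Rare classes were B or plasma-like cells at 0.321% (ascending) to 2.02% (arch). Schwann-like cells stood at 0.535% (ascending) to 1.18% (arch) with none among 344 descending cells (upper limit 1.07%). Lymphatic endothelial-like cells were 0.566% of the root library, with none in the ascending, arch and descending libraries (upper limits 0.394%, 0.618% and 1.07%). Cells in 3 clusters without a class name were 2.37% of root, 29.2% of ascending, 34.3% of arch and 8.43% of descending cells. Most of them formed 1 cluster led by STEAP4, CD36 and INPP4B. It carried all 6 pericyte markers and the smooth muscle gene SYNPO2 and held 31, 260, 172 and 27 cells from root to descending. Counted as SMC-like, it would bring that class to 14%, 44.8%, 45.2% and 25%. With a limit of 5% mitochondrial UMIs the SMC-like share was 2.77% in the root and 2.21% in the ascending library, and with at least 500 genes and at most 10% it was 32.5% in the arch. These shares describe CD45-negative, CD235a-negative cells that survived digestion, sorting and the filter. The filter and doublet removal kept 72.3%, 67.1%, 51.4% and 53.8% of barcodes from root to descending.

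**Figure D1:**
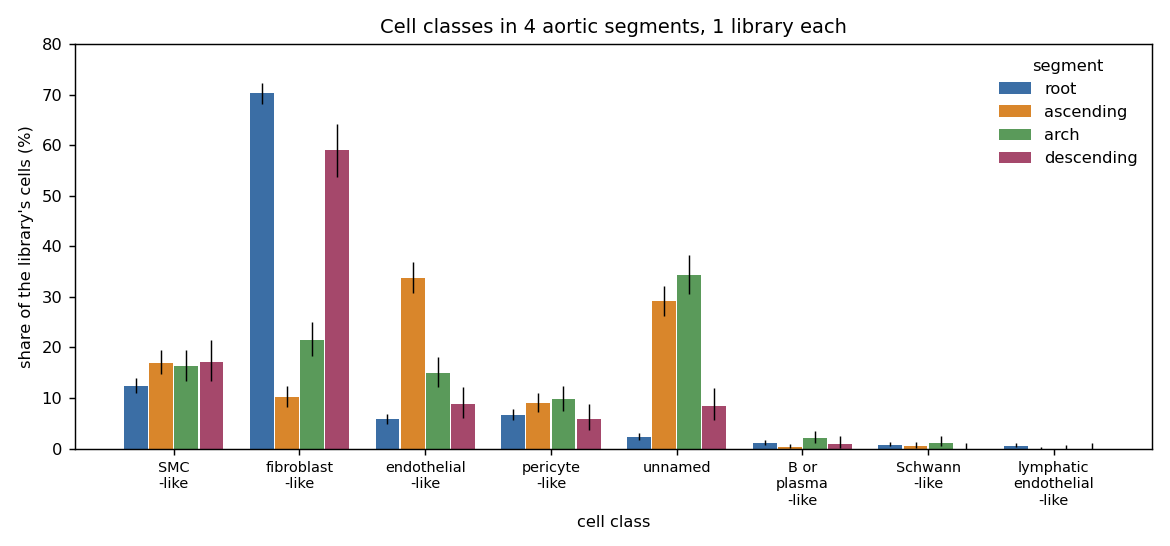
Share of each cell class (y axis, percent of the library's analysed cells) in the 4 segments (colours), with 1 library per segment; error bars are exact 95% binomial intervals and cover counting error only. Fibroblast-like cells stand at 70.2% in the root and 10.2% in the ascending aorta, and SMC-like cells between 12.4% and 17.2%.

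Summed SMC-like profiles came from 242 root, 159 ascending, 97 arch and 59 descending cells with 1630855, 1194952, 631712 and 392066 UMIs. In them, 8756 genes were measured. The class consisted of a larger and a smaller cluster, and the larger one held most SMC-like cells in every segment (201, 151, 53 and 39 cells). The smaller cluster, defined by CCN3, COMP, TNFRSF11B, MYH10, CYTL1, IGFBP2, FN1, ASPN, MICAL2 and RAMP1, made up 16.9% of SMC-like cells in the root, 5.03% in the ascending aorta, 45.4% in the arch and 33.9% in the descending aorta. Values within the larger cluster alone, an alternative chosen after the clusters were seen, are therefore given for many of the lists and genes. That cluster is part of the same sums from which the genes were picked. A gene that keeps its direction there is therefore not checked independently, and counting noise was not weighed.

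HOX genes, the transcription factors that mark position along the body axis, were low in root and high in descending SMC-like cells. All 5 measured members (HOXA3, HOXB2, HOXB3, HOXB4 and HOXB7) were lower in the root than in the mean of the other segments, with a median log2 value of -1.25 (-1.76 to -0.72) below matched random lists (percentile 0; -0.67 with no minimum beyond 1 UMI). All 5 were higher in the descending aorta, at 1.03 (0.37 to 1.56, percentile 99.98; 0.46 at clustering resolution 1.0). HOXB7 (ENSG00000260027, chromosome 17, 48607227 to 48633572, GRCh38) stood at 28.1 CPM in descending cells (14 to 50.2, 11 UMIs) and 4.18 CPM in ascending cells (1.36 to 9.77). It had 0 UMIs in root and arch cells, where 3 UMIs would be 1.84 and 4.75 CPM. It counted as measured through descending cells alone, so its higher value there was partly set by that rule. HOXA3 was highest in the arch, at 20.6 CPM (11 to 35.2), against 1.84 CPM in the root. HOXB2, the most abundant member, differed least, with 41.1 CPM in the root and 56.1 CPM in the descending aorta. HOXB4 stood at 10.4 and 38.3 CPM and HOXB3 at 7.97 and 30.6 CPM in these segments. Within the larger cluster 3 HOX genes remained measured and the medians were -1.12 in the root and 0.98 in the descending aorta. HOX medians in between were 0.24 (-0.14 to 0.57; 0.01 in the larger cluster) in the ascending aorta and -0.13 (-0.77 to 0.26; 0.18 in the larger cluster) in the arch.

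GATA4, a transcription factor of heart and outflow tract development, was detected in root SMC-like cells at 11 CPM (6.54 to 17.4, 18 UMIs), with 2 UMIs in ascending cells. It had none in arch and descending cells, where 0 UMIs allow up to 5.84 and 9.41 CPM, the latter overlapping the root interval. TCF21, a regulator of epicardium-derived lineages, ran from 327 CPM in the root and 130 CPM in the ascending aorta to 9.50 CPM in the arch and 10.2 CPM in the descending aorta. The cardiac and second heart field list as a whole had medians of 0.25 in the root (0.13 to 0.59, percentile 88.7) and -0.39 in the arch (-0.80 to -0.09, percentile 0.76; -0.12 in the larger cluster). TBX2 stood at 366 and 185 CPM in these segments, with FOXC1 running the other way, from 262 CPM in the root to 393 CPM in the descending aorta. Neural crest and pharyngeal arch regulators were low in the root, at -0.42 (-0.62 to -0.18, percentile 0) with 11 of 14 members lower. Among them FOXD1 stood at 63.8 CPM in descending cells against 4.75 to 6.13 CPM elsewhere. SOX9 had 0 UMIs in ascending cells and 17.8 CPM in the root, and EDNRA ran from 225 CPM in the root to 149 CPM in the arch. The 3 measured paraxial mesoderm regulators had a median of 0.71 in the root (0.42 to 1.02, percentile 99.0), where TCF15 reached 128 CPM against 31.7 to 43.4 CPM elsewhere; against the ascending aorta alone the median was -0.070. MEOX2 stood at 131 and 137 CPM in root and ascending cells and at 66.5 and 53.6 CPM in arch and descending cells.

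**Figure D2:**
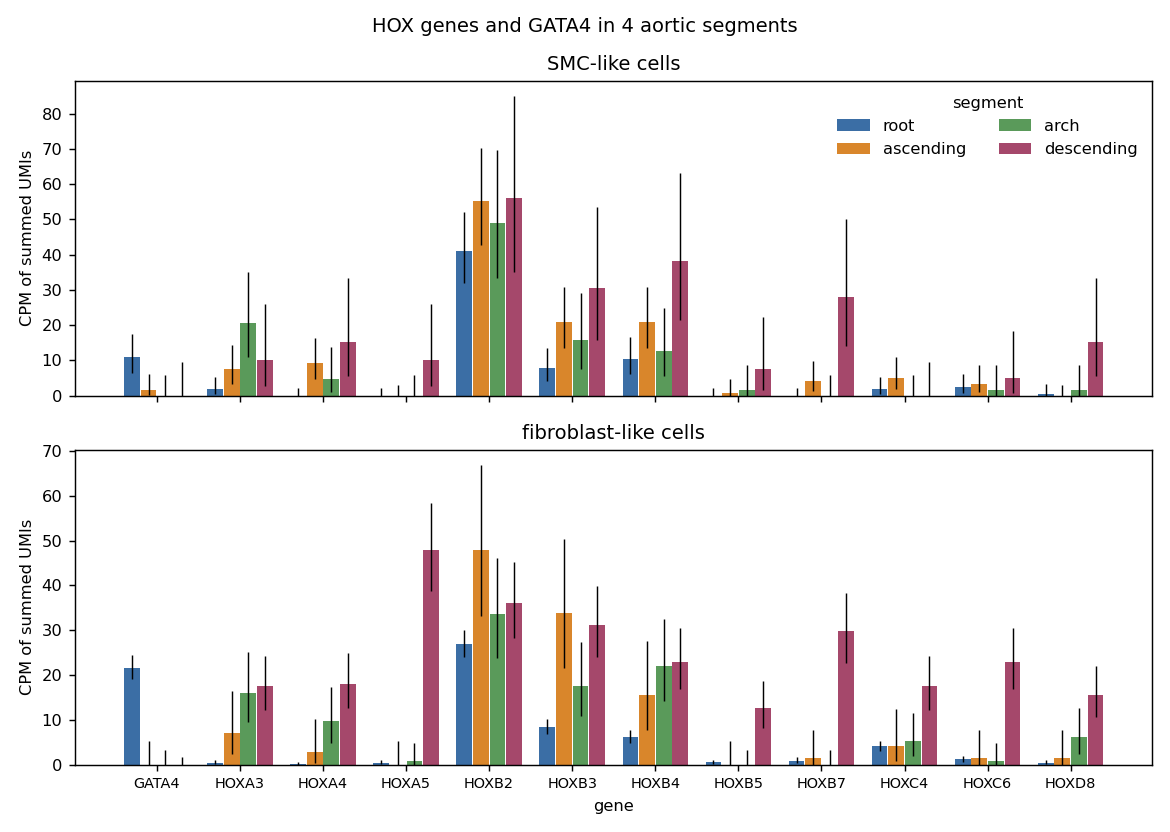
CPM (y axis) of GATA4 and 11 HOX genes (x axis) in summed SMC-like (top) and fibroblast-like cells (bottom) of the 4 segments (colours), with exact 95% Poisson intervals that cover counting error only. GATA4 appears at 11 CPM in root SMC-like and 21.7 CPM in root fibroblast-like cells, and HOXB7 at 28.1 and 29.8 CPM in descending cells of these classes.

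Extracellular matrix genes set the descending SMC-like profile apart. All 20 measured collagens were higher there than in the mean of the other segments, with a median log2 value of 1.07 (0.91 to 1.45, percentile 100). All 16 elastic fibre genes were too, at 0.90 (0.71 to 1.11, percentile 100). COL12A1 (ENSG00000111799, chromosome 6, 75084326 to 75206051, GRCh38), a collagen associated with fibrils, reached 247 CPM in descending cells, 4.88-fold above the arch (3.25 to 7.53). POSTN stood at 730 CPM and 3.55-fold (2.87 to 4.40), COL4A1 of basement membranes at 541 CPM and 3.08-fold (2.44 to 3.91), COL3A1 at 434 CPM and 2.19-fold (1.73 to 2.78) and COL1A1 at 406 CPM and 2.17-fold (1.70 to 2.78) above the arch. VCAN, a large proteoglycan, PCOLCE, an enhancer of procollagen processing, and the basement membrane proteoglycan HSPG2 were also among the 12 highest, with ratios of 1.98, 2.14 and 2.39. PLCG2 (1821 CPM, 2.60-fold), the contractile isoform ACTG2 (173 CPM, 2.25-fold), RGS5 (2803 CPM, 2.11-fold), a regulator of G protein signalling that also marks pericytes, and TM4SF1 (2.09-fold) completed the set. Within the larger cluster 10 of these 12 genes were still highest in the descending aorta: TM4SF1 3.68-fold, COL12A1 3.19-fold (80.2 CPM), ACTG2 2.54-fold, PCOLCE 2.49-fold, HSPG2 and RGS5 2.14-fold, PLCG2 1.68-fold, COL1A1 1.67-fold, COL4A1 1.60-fold and COL3A1 1.25-fold (18 UMIs). POSTN (1 UMI) and VCAN (0 UMIs) had too few counts there. The collagen median was 0.47 and the elastic fibre median 0.14 in that cluster.

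Contractile apparatus genes were slightly higher in descending cells, with 25 of 30 members above the mean of the other segments and a median of 0.22 (0.16 to 0.29, percentile 99.9). It was 0.27 within the larger cluster. ACTA2 and TAGLN, the most abundant members, stayed within narrow limits, from 3154 to 3576 CPM and from 7563 to 8672 CPM. The intermediate filament gene DES reached 53.6 CPM in descending cells against 11.1 to 14.7 CPM elsewhere. Proteoglycan and matricellular genes (0.73, 0.52 to 0.88, percentile 100; 0.48 in the larger cluster), matrix proteases and inhibitors (0.70, 0.41 to 0.93, percentile 100, 16 of 17 members) and heritable thoracic aortic disease genes (0.29, 0.18 to 0.57, percentile 99.4) also lay high. Among them were TIMP1 at 2609 CPM against 300 CPM in the ascending aorta and LOX, the enzyme that crosslinks elastin and collagen, at 30.6 CPM against 6.70 to 8.58 CPM elsewhere. TGF-beta responsive genes had a median of 0.22 (0.08 to 0.47, percentile 99.6), which was -0.01 within the larger cluster. NF-kappaB and inflammatory genes had one of 0.29 (0.02 to 0.48, percentile 99.3), which was -0.06 there. Nuclear-encoded oxidative phosphorylation genes were lower, at -0.18 (-0.27 to -0.12, percentile 0.705) with 28 of 35 members lower. Hypoxia and glycolysis genes were lower too, at -0.32 (-0.45 to -0.01, percentile 0.16; -0.16 in the larger cluster), with BNIP3 at 12.8 CPM against 28.5 to 41.2 CPM, but stood at 0.70 with at most 5% mitochondrial UMIs, when 4 ascending and 13 root SMC-like cells were left. The genes named as low in descending cells rested on few UMIs: the immediate early gene ARC was 10.8-fold lower than in the root (1.85 to 437, 1 UMI) and PPP4C 5.79-fold lower than in the arch (1.79 to 29.8, 3 UMIs). KLHDC3, UBE2D1, C12orf29, MRPS9, PRPF31, the growth factor gene FGF7, ADAM9, CSNK2A1, CYTL1 (which defines the smaller cluster) and ACYP1 followed at ratios of 3.50 to 2.66, all below the 4.03-fold that counting noise alone gave for the top gene.

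Ascending SMC-like cells showed the opposite matrix profile in the whole class, but, matrix proteases apart, not within the larger cluster. All 16 elastic fibre genes were lower than in the mean of the other segments (-0.97, -1.17 to -0.68, percentile 0). So were 18 of 20 collagens (-0.69, -1.03 to -0.66, percentile 0), 19 of 26 proteoglycan and matricellular genes (-1.04, -1.19 to -0.83, percentile 0), and 14 of 17 matrix proteases and inhibitors (-0.65, -1.03 to -0.56, percentile 0). In the larger cluster alone these medians were 0.12, -0.02, 0.32 and -0.52. Fibroblast markers were low too, at -1.37 with 11 of 12 members lower, and at -1.04 over the 7 members measured in the larger cluster. Some of these, such as C3 (90 root UMIs and 1 ascending UMI), passed the minimum there through root cells alone or nearly so. The value of -1.04 was thus partly set by that rule. EFEMP1, a fibulin, stood at 68.6 CPM against 139 to 390 CPM elsewhere. COL8A1 stood at 15.9 CPM against 57.6 to 191 CPM, and the aggrecanase ADAMTS4 at 62.8 CPM against 226 to 468 CPM. VCAN was 5.82-fold lower than in the root (4.59 to 7.48), but had at most 5 UMIs in any segment of the larger cluster. TNFAIP6, a hyaluronan-binding protein (13.9-fold, 3.60 to 119, 2 UMIs), PTGIS, the prostacyclin synthase (6.32-fold), S100A10, PCOLCE2, MEG3, PRSS23 and IGFBP3 were likewise low in the whole class with too few UMIs to compare within the larger cluster. By contrast ZNF331 (3.88-fold, 2.81 to 5.43), the anchoring protein AKAP12 (4.14-fold), EMP1 (4.76-fold) and the somatostatin receptor SSTR2 (4.92-fold) were lowest in the ascending aorta in the whole class and in the larger cluster, where the ratios were 5.62, 1.27, 4.02 and 5.51. For AKAP12 the larger-cluster ratio rested on 45.1 CPM against 57.1 CPM in the arch (23 UMIs). It lay below what counting noise alone gave in the whole class, 1.61-fold for the top and 1.35-fold for the last of 12 genes. EMP1 and SSTR2 had 7 ascending UMIs each in the larger cluster. SSTR2 and ADAMTS4 were among the leading genes of a pericyte-like cluster.

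Genes high in ascending cells included PTGS2, the inducible prostaglandin synthase, at 132 CPM and 2.46-fold above the arch (1.69 to 3.67). The metallothionein MT1X stood at 502 CPM and 2.17-fold above the root (1.90 to 2.47), while the metallothioneins as a list stood at -0.21 (-0.29 to -0.00, 4 of 5 lower; -0.50 in the larger cluster). SBF2, FBXL13, EGLN3 (an oxygen-sensing prolyl hydroxylase), PRPH, SBSPON, HRH2 (a histamine receptor), SELENOP (a selenium carrier), SLC38A1 and LDB3 followed with ratios of 1.97 to 1.75, of which those of SBF2 (1.0 to 4.31) and SLC38A1 (0.93 to 3.78) had intervals reaching 1. All 12 genes picked by the rule were also highest in the ascending aorta within the larger cluster. That cluster held 151 of the 159 ascending SMC-like cells, and any ratio above 1 counted, so this is no independent check. Unfolded protein response genes lay low, at -0.65 (-0.76 to -0.43, percentile 0; -0.19 in the larger cluster), with the chaperone HSP90B1 at 256 CPM against 602 CPM in the descending aorta. Interferon response and antigen presentation genes lay low at -0.24 (-0.32 to -0.12, percentile 1.83; -0.14 in the larger cluster). Vasoactive receptors and ion channels were higher, at 0.21 (0.08 to 0.37, percentile 99.9; 0.09 in the larger cluster), with GUCY1A1, a subunit of the nitric oxide receptor, at 472 CPM against 328 CPM in the arch. Immediate early genes lay higher in the ascending aorta, at 0.25 (0.19 to 0.33, percentile 99.9; -0.07 in the larger cluster). TGF-beta responsive genes (-0.34, -0.49 to -0.15, percentile 0.05) and NF-kappaB and inflammatory genes (-0.26, -0.47 to -0.00, percentile 1.73) lay lower, with -0.00 and -0.02 in the larger cluster. Osteochondrogenic genes had a median of -0.33 (-0.62 to -0.02, percentile 2.36), with the calcification inhibitor MGP at 4178 CPM against 6646 CPM in the root, 17150 CPM in the arch and 19180 CPM in the descending aorta. That median was 0.12 in the larger cluster, 0.089 with no minimum beyond 1 UMI and 0.19 with a minimum of 50 CPM and 30 UMIs. The vasoactive median was -0.11 with no minimum beyond 1 UMI, and the NF-kappaB median 0.085 against the arch alone.

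Root SMC-like cells were marked by some, but not all, of the genes that are also typical of fibroblasts, together with stress-response genes. The secreted phospholipase PLA2G2A was 9.38-fold above the descending aorta (3.59 to 34.8). The complement genes CFD and C3 were 9.17-fold (5.42 to 16.9) and 5.89-fold (2.23 to 22.1) above it. The apolipoprotein gene APOD was 6.02-fold above the arch (3.7 to 10.5) and DCN, the proteoglycan decorin, 3.62-fold above the ascending aorta (3.22 to 4.07; 1.77-fold in the larger cluster). The fibroblast markers as a list had a median of 0.95 in the root (0.80 to 1.15, percentile 100; within the larger cluster 1.99 over its 7 measured members and 1.21 over all 12), -1.37 in the ascending aorta (-1.52 to -1.02, percentile 0) and -0.63 in the arch (-0.96 to -0.32, percentile 0.01; -1.18 within the larger cluster, 2.04 with at most 5% mitochondrial UMIs). In the descending aorta it was 0.37 (-0.13 to 0.66, percentile 98.3; 0.59 within the larger cluster). Besides CFD, C3, APOD and DCN, the members LUM, SERPINF1 and PI16 were highest in the root. PDGFRA (26.4 CPM in the root, 58.6 CPM in the arch), DPT and SFRP2 (7.36 and 88.7 CPM) were instead highest in the arch. FBLN1 and PODN were highest in the descending aorta. Values over the 7 members measured in the larger cluster were partly set, in every segment, by members measured there mainly through root cells. The root library was also the one with the largest share of fibroblast-like cells. In root endothelial-like cells, taken as a reference, APOD reached 86.6%, PI16 152% and DCN 5.36% of the level in root SMC-like cells (21.2% for DCN against the larger cluster). PI16 was found in endothelial-like cells of every segment, at 26.1, 42.9, 25.9 and 86.8 CPM from root to descending. Root pericyte-like cells reached 22.0% for DCN, 79.0% for SERPINF1 and 211% for CFD. The WNT inhibitor SFRP4, the cartilage link protein HAPLN1, CD36, RARRES1, TCF15, VPS37B and APOLD1 were the other genes named as high, at 5.41- to 2.77-fold. SFRP4 and HAPLN1 had 0 root UMIs in the larger cluster, where the other 10 of 12 remained highest in the root.

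All 16 heat shock genes were higher in the root than in the mean of the other segments, at a median of 0.41 (0.38 to 0.47, percentile 100), with HSPA6 at 1139 CPM against 357 CPM in both the ascending and the descending aorta. Immediate early genes, which dissociation of tissue can induce, were higher in 23 of 24 members, at 0.42 (0.33 to 0.52, percentile 100), and all 5 metallothioneins at 0.59 (0.53 to 0.69, percentile 99.8). NF-kappaB and inflammatory genes (0.34, 0.16 to 0.57, percentile 99.0) and SMC transcriptional regulators (0.33, 0.24 to 0.46, percentile 99.98) lay high too. Examples were CEBPD at 1295 CPM and NR4A1 at 993 CPM. Collagens (-0.30, -0.40 to -0.17, percentile 0.04) and elastic fibre genes (-0.24, -0.42 to -0.02, percentile 0.16) lay below the other segments, but above the ascending aorta taken alone (0.32 and 0.66). Genes named as low in the root had small ratios: the fucose pathway enzyme GMDS was 2.09-fold (1.35 to 3.27) and the ubiquitin ligase HERC2 1.91-fold (1.32 to 2.77) below the ascending aorta, followed by POSTN, CXXC5, SLC7A2, PCDH10, CEP126, RAMP1, ACTG2, SYNPO, ANGPT1 and NPY1R at 1.76- to 1.48-fold. The intervals of PCDH10, CEP126, ACTG2 and NPY1R reached 1. Counting noise alone gave 1.54-fold for the top gene, which 6 of the 12 exceeded, and within the larger cluster RAMP1 and SYNPO were no longer lowest in the root.

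Arch SMC-like cells had fewer transcripts of immediate early genes, vasoactive receptors and SMC markers in the whole class and the larger cluster. Immediate early genes were lower in 20 of 24 members, at -0.56 (-0.66 to -0.41, percentile 0; -0.34 within the larger cluster). In the smaller cluster, 45.4% of arch SMC-like cells, the arch medians had the other sign: 0.36 for immediate early genes, 0.22 for vasoactive receptors, 1.24 for SMC markers and 0.78 for contractile genes. The median percentage of mitochondrial UMIs in SMC-like cells was 8.86, 9.58, 6.54 and 7.71 from root to descending. Among immediate early genes in the whole class, ZFP36 was 1.99-fold (1.76 to 2.26) and EGR1 1.92-fold (1.71 to 2.17) below the root, and KLF2, a factor induced by shear stress in endothelium, 1.88-fold (1.61 to 2.2) below the descending aorta. Vasoactive receptors and ion channels had a median of -0.40 (-0.47 to -0.19, percentile 0.01; -0.17 within the larger cluster), and the vasopressin receptor AVPR1A stood at 11.1 CPM, 4.83-fold below the descending aorta (1.98 to 13.5). The chemokine CCL8 was 3.56-fold lower than in the ascending aorta (2.37 to 5.56). RIPOR2, WFDC2, COL27A1, SLMAP, the chemokine receptor ACKR3, SOCS2 and DCUN1D3 completed the genes named as low at 2.82- to 1.89-fold, with an interval reaching 1 for DCUN1D3 (0.98 to 3.95). Of the 12, 7 exceeded the 1.98-fold of counting noise, and all 12 were also lowest in the arch within the larger cluster. AVPR1A and CCL8 were among the leading genes of a pericyte-like cluster. The contractile list was lower in the arch, at -0.18 (-0.24 to -0.10, percentile 0.17; -0.31 within the larger cluster), but stood at 0.017 with at most 5% mitochondrial UMIs and at 0.067 after thinning to 2000 UMIs per cell. SMC markers stood at -0.31 (-0.49 to -0.23, percentile 0.21) and pericyte markers at -0.52 (-0.73 to -0.15, percentile 0.45; -0.20 within the larger cluster), the latter at 0.069 with at most 20% mitochondrial UMIs and 0.15 with no doublets removed.

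Genes named as high in the arch included SFRP2, a WNT modulator and one of the fibroblast markers (4.96-fold above the descending aorta, 2.26 to 12.9), and TSPAN8 (4.69-fold above the ascending aorta, 2.96 to 7.64). The others were the protease inhibitor SPINT2 (3.00-fold), S100A10 (2.40-fold), the aryl hydrocarbon receptor AHR (2.10-fold), TMEM167A, KRT7, MEG3, REXO2 and CYBRD1, besides TNFRSF11B and IGFBP2, which define the smaller cluster. Within the larger cluster 5 of the 12 had too few UMIs and 3 were not highest in the arch. AHR (102 CPM) was 1.78-fold and TSPAN8 1.56-fold above the next segment there, and SPINT2 (1.07-fold, 6 UMIs) and TMEM167A (1.0-fold) were about level with it. Proteoglycan and matricellular genes had a median of 0.61 (0.37 to 0.80, percentile 100) in the whole class and -0.41 in the larger cluster, and -0.084 against the descending aorta alone. Osteochondrogenic genes, some of which define the smaller cluster, had medians of 0.66 (0.28 to 0.94, percentile 100) and 0.31. SMC transcriptional regulators (-0.25, -0.39 to -0.06, percentile 0.37; -0.12 in the larger cluster), NF-kappaB and inflammatory genes (-0.35, -0.57 to -0.23, percentile 0.26) and metallothioneins (-0.35, -0.74 to -0.17, percentile 1.90; -0.17 in the larger cluster) lay low. Heat shock genes did so at -0.16 (-0.21 to -0.10, percentile 1.11; 0.12 in the larger cluster).

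**Figure D3:**
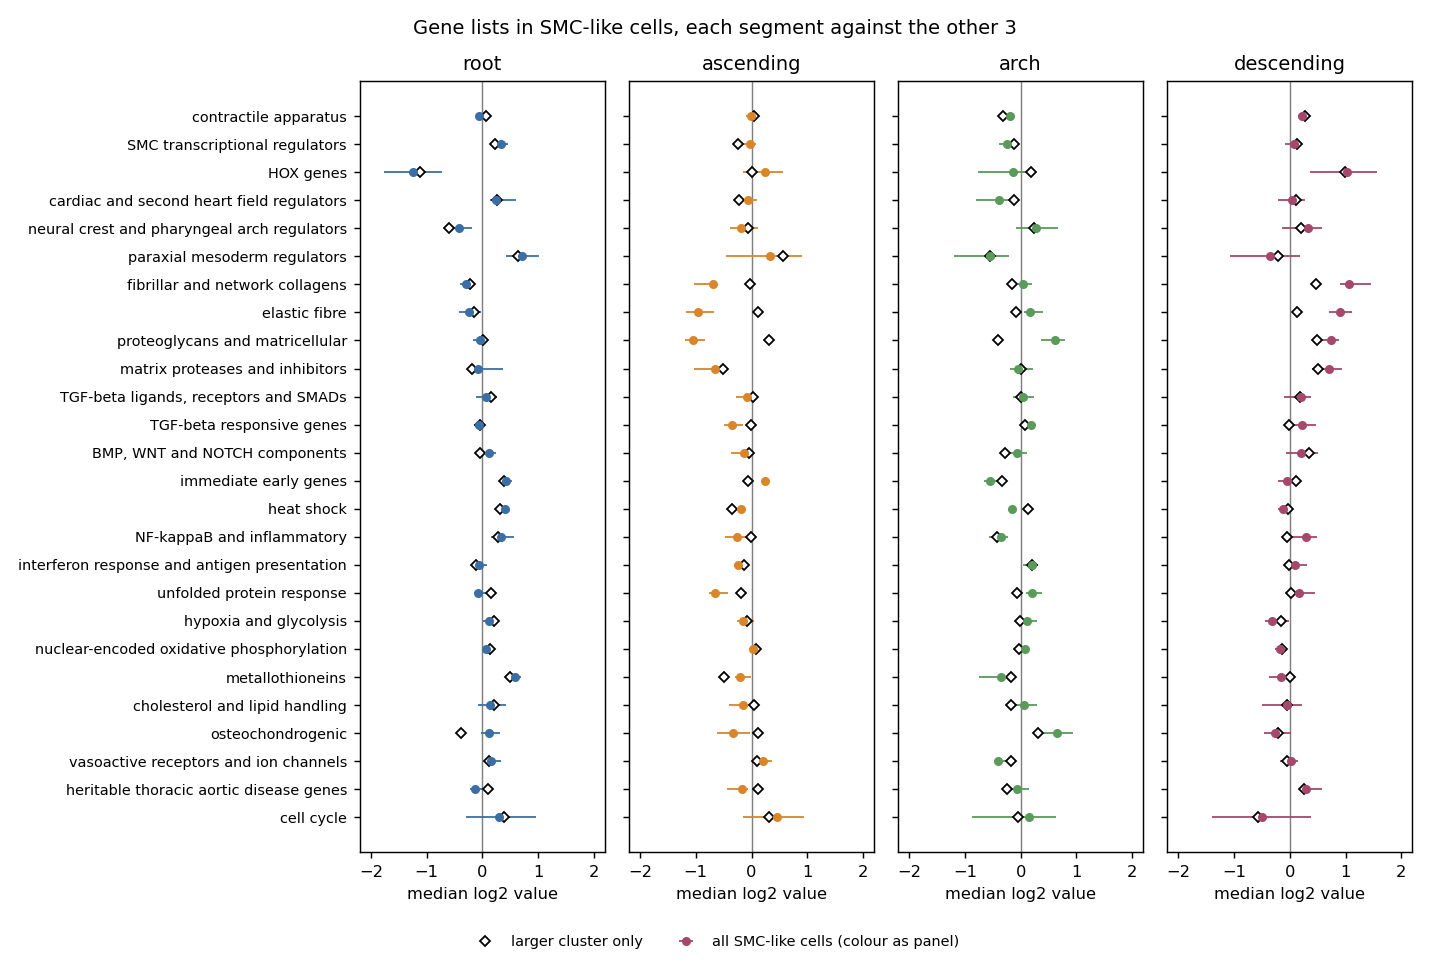
Median log2 value (x axis) of the measured members of 26 gene lists (y axis) in SMC-like cells of each segment against the other 3; filled points are the whole class with 95% intervals of counting error only, and open diamonds the larger cluster alone. Collagen, elastic fibre and proteoglycan medians in the ascending aorta move from -0.69, -0.97 and -1.04 to -0.02, 0.12 and 0.32, while the HOX median in the root stays at -1.25 and -1.12.

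Lists that set no segment apart by more than matched lists were TGF-beta ligands, receptors and SMADs (medians of -0.09 to 0.19 across segments, with SMAD3 at 26.9 CPM in the arch against 7.65 CPM in the descending aorta) and BMP, WNT and NOTCH components (-0.14 to 0.20, with NOTCH3 at 388 to 499 CPM). So were cholesterol and lipid handling (-0.16 to 0.13, with the fatty acid carrier FABP4 at 1288 CPM in the root and 428 CPM in the descending aorta) and the 3 measured cell cycle genes (-0.50 to 0.46, with PCNA at 10.2 to 23.9 CPM). Markers of endothelial, lymphatic endothelial, mast, neutrophil, erythroid, cardiomyocyte, mesothelial and platelet cells had 0 measured members in SMC-like cells. Those of macrophages, T or NK cells, B or plasma cells and adipocytes had 1 member each and Schwann markers 2, so that no median was computed for them.

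Genes ordered along the vessel were hardly more frequent than chance. In SMC-like cells 845 of 8756 measured genes (9.65%, 9.04 to 10.3%) ran in 1 direction from root to descending aorta, against 8.33% for random orders. The true order ranked 5th of 12 possible orders, the highest being 11.8% for ascending, root, arch, descending. Among the 845 genes, DCN was 17.4-fold higher in the root than in the descending aorta. FRK, ZNF302, ACYP1, RASD1, SMIM3, RGCC, TMEM51, FABP4 and MLH3 were 4.76- to 2.95-fold higher, FABP4 running from 1288 to 428 CPM. In the other direction, POSTN was 22.9-fold and COL12A1 8.23-fold higher in the descending aorta than in the root. They were followed by ITGA11, an integrin that binds collagen, SSH1, STXBP4, NPY1R, PLCG2, PDXDC1, CXXC5 and FBN1, the fibrillin of elastic fibre microfibrils, at 4.58- to 2.73-fold. Within the larger cluster DCN still ran from 269 CPM in the root to 34.9 CPM in the descending aorta, whereas POSTN stood at 0, 19.1, 9.92 and 3.49 CPM from root to descending.

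Fibroblast-like cells were compared in the same way from 1366 root, 95 ascending, 128 arch and 203 descending cells with 12008382, 710755, 1132850 and 2049662 UMIs. Different clusters held most of them: 1030 of the root cells lay in a cluster of 1046 cells, and 77 more in a cluster from the root alone. The ascending, arch and descending cells lay mostly in another cluster (90, 118 and 188 cells, with 112 root cells). A cluster of this kind may be the library rather than a cell type. The median log2 value of all 9783 measured genes was -0.29 in the root and 0.09, 0.15 and 0.05 in the ascending, arch and descending aorta, so that list values are given relative to it.

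HOX genes again separated the descending aorta in this class: all 11 measured members were higher there, at a relative median of 1.97 (1.55 to 2.38, percentile 100). It was 1.01 with a pseudocount of 10 CPM, 1.19 against the arch alone and 1.46 with no minimum beyond 1 UMI. Members such as HOXA5, HOXB7 and HOXC6 counted as measured through descending cells alone, so the count of 11 was partly set by that rule. All 11 were lower in the root (-1.13, -1.25 to -0.78, percentile 0.03), with -0.82 in the ascending aorta and -0.38 in the arch. HOXA5 (ENSG00000106004, chromosome 7, 27141052 to 27143668, GRCh38) stood at 47.8 CPM in descending cells (98 UMIs), with 5 UMIs in the root, 1 UMI in the arch and 0 UMIs in the ascending aorta. HOXB7 stood at 29.8 CPM, with 0 UMIs in the arch and 1 UMI in the ascending aorta. HOXC6 reached 22.9 CPM against 0.883 to 1.41 CPM elsewhere, HOXA4 18.1 CPM, HOXC4 17.6 CPM, HOXD8 15.6 CPM and HOXB5 12.7 CPM. HOXA3 stood at 15.9 CPM in the arch and 17.6 CPM in the descending aorta against 0.416 CPM in the root, HOXB4 at 22.1 and 22.9 CPM against 6.16 CPM. HOXB2 and HOXB3 were highest in the ascending aorta at 47.8 and 33.8 CPM. FOXD1 was at 67.3 CPM in descending cells and at most 9.85 CPM elsewhere. GATA4 was found at 21.7 CPM in root fibroblast-like cells (19.1 to 24.5, 260 UMIs) and had 0 UMIs in the other segments, whose floors were 4.22, 2.65 and 1.46 CPM. Cardiac and second heart field regulators were higher in the root (0.40, 0.24 to 0.61, percentile 99.6) and lower in the descending aorta (-0.54, -0.86 to -0.26, percentile 0.05; 0.080 against the arch alone). TCF21 stood at 55.3 and 54.9 CPM in root and ascending cells against 2.65 and 0.976 CPM in arch and descending cells.

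Genes named as high in root fibroblast-like cells were CCBE1 (30.1 CPM, with 1 UMI each in the ascending aorta and the arch and 0 in the descending aorta), the homeobox gene LHX9 (16.5-fold, 7.53 to 45.2), the adhesion molecule CHL1 (16.3-fold), the chemokine CCL21 (15.4-fold, 4.23 to 127), the growth factor PTN (2097 CPM, 13.6-fold, 11.2 to 16.5) and CPXM1 (11.7-fold). PTN was among the leading genes of the cluster that was mostly root cells. CPXM1 was among those of another fibroblast-like cluster with 147 root cells among 161. CCL21 is also a marker of lymphatic endothelium. In the ascending aorta CYTL1 (6.21-fold, 4.64 to 8.44), CARTPT, MYOC (3.42-fold), the neurotrophin receptor NTRK3, COMP and SLC1A7 were named. In the arch these were THSD4 (6.54-fold, 3.02 to 16.9), the WNT inhibitor DKK1 (4.15-fold), the potassium channel KCNMA1, ANGPTL7, SERTAD4 and AKR1C2. In the descending aorta, the HOX genes were followed by PTHLH (10.1-fold, 5.24 to 22.3), SKAP2 (8.46-fold), which lies beside the HOXA cluster, the imprinted RNA H19 (8.07-fold) and the metallothionein MT1G (7.99-fold). Stress genes differed strongly in this class: heat shock genes had relative medians of 1.43, -1.43, -0.82 and 0.85 and immediate early genes of 1.11, -0.92, -0.90 and 0.80 from root to descending.

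Collagens, proteoglycans and elastic fibre genes in fibroblast-like cells were low in the root and high in the ascending aorta, whereas matrix proteases and inhibitors were low in the ascending aorta (-0.35, -0.46 to -0.16, percentile 0.83). Collagens stood at -0.71 in the root (-0.79 to -0.59, percentile 0) and 0.69 in the ascending aorta (0.36 to 0.91, percentile 100). Examples were COL1A2 at 308 CPM in the root and 1481 CPM in the descending aorta and COL21A1 at 106 CPM in the ascending aorta against 4.0 CPM in the root. Proteoglycan and matricellular genes stood at -0.80 and 0.53, with BGN at 72.0 and 981 CPM. Elastic fibre genes stood at -0.47 and 0.32, with ELN at 81.9 and 423 CPM, and osteochondrogenic genes at -1.23 and 1.27. The contractile list (-0.87 and 0.52) and vasoactive receptors (-0.70 and 0.76) followed the same direction. So did SMC markers (-0.81 and 0.82), Schwann markers (-1.10 and 1.01) and, in the root, pericyte markers (-1.06) and TGF-beta responsive genes (-0.76, and 0.05 in the ascending aorta, with CCN2 at 130 CPM against 1171 CPM in the ascending aorta). NF-kappaB and inflammatory genes were high in the root (1.27, 1.06 to 1.38, percentile 100), where CXCL1, a leading gene of the cluster from the root alone, reached 48.0 CPM against 0.488 CPM in the descending aorta. All 7 metallothioneins were high in the descending aorta (1.14, 0.96 to 1.37, percentile 100) and low in the ascending aorta (-1.27). APOE, PLIN2 and APOD were highest in the root, at 1878, 551 and 11970 CPM.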

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

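The tests on carried-over RNA for DCN, LUM, SERPINF1, the other and all fibroblast markers (in the whole class or the larger cluster), GATA4 and the HOX genes, and the tests on the cluster mix for the fibroblast markers, were chosen after the results were seen. The doublet test, the tests on the cluster mix for the matrix lists and the carry-over test for the descending collagens were set before the tested values were computed, although the list medians and the cluster mix were known by then.

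Several gene lists lay on opposite sides of 0 in SMC-like and fibroblast-like cells of the same segment, and the differences were not tested. In the ascending aorta, collagens stood at -0.69 in SMC-like and 0.69 in fibroblast-like cells (difference -1.38). Elastic fibre genes stood at -0.97 and 0.32 (difference -1.28), proteoglycan and matricellular genes at -1.04 and 0.53 (-1.57) and osteochondrogenic genes at -0.33 and 1.27 (-1.60). Fibroblast markers stood at -1.37 and 0.14 (-1.51), and immediate early genes ran the other way at 0.25 and -0.92 (1.17). In the arch, contractile genes stood at -0.18 and 0.35 (-0.53), vasoactive receptors at -0.40 and 0.36 (-0.77) and pericyte markers at -0.52 and 0.60 (-1.12). In the descending aorta, contractile genes stood at 0.22 and -0.18 (0.40) and hypoxia and glycolysis genes at -0.32 and 0.24 (-0.56). Fibroblast-like values are relative to the median of all genes. The ascending SMC-like values for elastic fibre, proteoglycan, osteochondrogenic and immediate early genes had the other sign within the larger cluster, and that for collagens nearly vanished there.

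A total of 41 cells were B or plasma-like although CD45-positive cells had been gated out. They carried a median of 28193 UMIs per cell, IGKC at 320100 CPM, JCHAIN at 20180 CPM and 2 UMIs of PTPRC, the gene of CD45. No explanation was tested for them.

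The first pattern weighed is the excess of fibroblast markers, taken as a list, in root SMC-like cells. It was seen in the library where fibroblast-like cells were most frequent. With root endothelial-like cells as the reference, carried-over fibroblast RNA that reaches all cells alike was excluded in the whole class as the whole source of DCN, LUM and SERPINF1. The reference reached 5.36% (3.72 to 7.48%), 0% (0 to 2.93%) and 8.73% (3.47 to 18.3%) of the SMC-like level. It was also excluded for all markers summed (19.1%, 16.8 to 21.7%, with DCN as 1737 of 3539 UMIs). By contrast, APOD reached 86.6% (67.1 to 111%) and PI16 152% (76.75 to 290.5%), which met the limit for a fit, and CFD stayed open at 41.3% (32.4 to 52.1%). PI16 was also found in endothelial-like cells of the other segments, so this reference may not lack every marker by itself. Root pericyte-like cells had 1 PI16 UMI (1.45 CPM), against 26.1 CPM in root endothelial-like cells. The PI16 value is therefore no evidence for RNA that reaches all cells alike. Carry-over stays open for the summed markers other than DCN (32.4%, 28.1 to 37.3%). Against the larger cluster it stays open for these (46.8%, 40.3 to 54.1%), for all markers summed (40.1%, 35.0 to 45.9%) and for DCN (21.2%, 14.5 to 30%). LUM is open there too (0%, 0 to 194%, 6 UMIs), but not SERPINF1 (11.4%, 4.49 to 24%). None of the open intervals lies wholly below 25% or above 50%, the limits set for exclusion and for a fit. The larger cluster held 378 of the 1737 root DCN UMIs and 6 of the 337 root LUM UMIs. The exclusions of DCN and LUM in the whole class therefore rest mostly on root cells of the smaller cluster. Root pericyte-like cells reached more of the SMC-like level, 22.0% (18.6 to 25.8%) for DCN, 9.84% (5.32 to 16.7%) for LUM, 79.0% (59.5 to 104%) for SERPINF1 and 61.3% (57.0 to 65.9%) for all markers. Single markers ran from 0% for SFRP2 (0 to 85.3%) to 211% for CFD (186 to 239%). This leaves open RNA from fibroblasts that reached mural cells more than endothelial-like cells. A different mix of the SMC-like clusters was excluded as the whole source, with a root median in the larger cluster of 1.21 (0.83 to 1.81) over all 12 members measured in the whole class. Over the 7 members measured in that cluster it was 1.99 (1.63 to 2.94). Some of these, such as C3 and APOD, passed the minimum there through root cells alone or nearly so, which raises that value. Doublets were excluded as scored, with a median of 1.11 (0.95 to 1.34) without the 10% of cells of highest doublet score. A regional or donor difference remains untested.

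The second pattern is the low matrix expression of ascending and the high matrix expression of descending SMC-like cells, taken over the collagen, elastic fibre, proteoglycan and TGF-beta responsive lists, which were picked after the medians were seen. In ascending cells their mean of -0.76 became 0.10 (-0.03 to 0.20) in the larger cluster and 0.50 (0.33 to 0.62, 8 cells) in the smaller one. The smaller cluster made up 5.03% of ascending SMC-like cells, so these values meet the limit set for a different mix of the clusters. However, the clusters were drawn from the same counts, and CCN3, COMP, FN1 and ASPN, which lead the smaller one, belong to the tested lists. Leaving out cells grouped partly by such genes could shrink the difference by itself. The values therefore cannot tell a mix of cell types from a different level of these genes. In descending cells the mean of 0.73 became 0.27 (0.11 to 0.40), an interval that spans 0.2, the limit set for a mix effect, without passing 0.4, the limit set against it, so part of the excess may come from the mix. With matrix proteases in place of TGF-beta responsive genes the values were -0.02 (-0.13 to 0.17) and 0.40 (0.23 to 0.52), the latter above 0.2 but reaching below 0.4, which leaves the mix undecided too. Carried-over fibroblast RNA that reaches all cells alike was excluded for descending collagens other than the COL4, COL15 and COL18 genes, since endothelial-like cells reached 2.25% of the SMC-like level (1.35 to 3.53%), whereas they reached 33.0% for COL4A1 (22.6 to 46.9%) and pericyte-like cells 70.2% for the tested collagens (63.2 to 77.9%).

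The third pattern is GATA4 in root and HOX genes in descending SMC-like cells, both of which were also seen in fibroblast-like cells of these segments. Carried-over fibroblast RNA would bring DCN in the same proportion, and was excluded for both. GATA4 stood at 51.0% (29.7 to 82.2%) of its fibroblast-like level against 10.1% (9.65 to 10.6%) for DCN in the root, and the summed HOX genes stood at 77.3% (61.8 to 95.8%) against 0.507% (0.325 to 0.754%) for DCN in the descending aorta. Whether donors or libraries differ in these genes for other reasons could not be tested with 1 library per segment, so the pattern is left as a measured difference.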

How the results depend on the processing

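Alternatives that use 1 of the SMC-like clusters or count the unnamed cluster as SMC-like, and all alternatives for the shares of the other classes, were chosen after seeing the data. So was the choice of which lists have all moved values printed (contractile, HOX in root, collagens, elastic fibre and proteoglycans in SMC-like cells, and HOX in fibroblast-like cells), since the medians were known by then. The overlap of named genes is given as a total per setting, a form chosen after the overlaps per segment were seen. Of those overlaps, 45 of 112 in SMC-like and 30 of 44 in fibroblast-like cells stayed within 1.5 times. A list counts as called when its interval excludes 0 and its percentile lies in the outer 5%. Of 47 called SMC-like medians, 40 to 47 kept their sign under the alternatives fixed before the data were examined and the larger cluster alone kept 39, and of 67 fibroblast-like medians, 58 to 67. Of 1796 SMC-like medians under all alternatives, 1354 stayed within their counting interval, 396 moved and 46 changed sign after being called, and of 1440 fibroblast-like medians 1126, 304 and 10 did. The cells kept (1897, 813, 704 and 421 with at least 500 genes and at most 10% mitochondrial UMIs) and the share of genes in vessel order (9.55% and 9.80%) stayed in range. A minimum of 1000 genes equalled the filter in use and moved nothing, and HBB had 0 UMIs, so it added nothing to the marker exclusion. Descending SMC-like values rest on 59 cells. Except where a setting leaves fewer cells or genes, the cause of a change was not tested.

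With at most 5% mitochondrial UMIs, the SMC-like share was 2.77% in the root and 2.21% in the ascending aorta. All SMC-like medians under this limit rest on sums of 13 root, 4 ascending, 31 arch and 18 descending cells, and ascending medians were -4.79 for elastic fibre and -3.51 for proteoglycan genes. Then 7 of 96 SMC-like and 8 of 24 fibroblast-like genes were still named. Signs changed for arch contractile genes (0.017), arch fibroblast markers (2.04) and descending hypoxia genes (0.70), and in fibroblast-like cells for ascending BMP, WNT and NOTCH components (-0.0068) and fibroblast markers (-0.18). With at least 500 genes and at most 10%, shares were 9.65%, 14.4%, 32.5% and 23.3% from root to descending. Medians were 0.30 for descending contractile genes, 0.80 for descending collagens, -0.61 for ascending elastic fibre and -0.64 for ascending proteoglycan genes. Then 27 SMC-like and 14 fibroblast-like genes were still named, and descending interferon genes of fibroblast-like cells stood at 0.10. With at most 20%, ascending proteoglycans stood at -0.78 and arch pericyte markers at 0.069, and with no doublets removed at -0.83 and 0.15. At resolution 1.0, shares were 13.2% (ascending) and 13.1% (descending) and descending contractile genes stood at 0.15.

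Of 20 shares each, 15 of fibroblast-like, 11 of endothelial-like and 13 of pericyte-like cells stayed within their intervals. With at most 5% mitochondrial UMIs, fibroblast-like cells were 17.1% in the ascending aorta, 29.4% in the arch and 64.6% in the descending aorta, endothelial-like cells 9.36% (root) and 54.1% (ascending), and pericyte-like cells 0.213% (root), 17.1% (ascending) and 17.5% (arch). With at least 500 genes and at most 10%, fibroblast-like cells were 72.9% (root) and 13% (ascending), and endothelial-like cells 37.3% (ascending), 11.8% (arch) and 5.94% (descending). With no doublets removed, endothelial-like cells were 2.21%, 16.6%, 4.83% and 4.05% from root to descending. At resolution 1.0, pericyte-like cells were 8.53%, 21.6%, 17.6% and 11.3%.

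With the mean of each cell's CPM, descending contractile genes stood at 0.34, ascending elastic fibre at -0.55, and 60 SMC-like genes were still named. Thinned to 2000 UMIs, 28 SMC-like and 7 fibroblast-like genes were still named, ascending elastic fibre stood at -0.47, ascending proteoglycans at -0.78, arch contractile genes at 0.067 and arch pericyte markers of fibroblast-like cells at -0.14. Without cells holding PECAM1, PTPRC, PDGFRA or HBB, 54 were still named. With 100 or 50 UMIs as naming minimums 40 SMC-like and 14 fibroblast-like genes were still named, and with none 35 and 12. A pseudocount of 10 CPM gave 0.86 for descending collagens and 1.01 for descending HOX genes of fibroblast-like cells. With no minimum beyond 1 UMI, HOX genes stood at -0.67 in root SMC-like and 1.46 in descending fibroblast-like cells, ascending osteochondrogenic genes at 0.089, ascending vasoactive receptors at -0.11 and arch cholesterol genes of fibroblast-like cells at 0.042. With 50 CPM and 30 UMIs, descending collagens stood at 1.74, ascending osteochondrogenic genes at 0.19 and root matrix proteases of fibroblast-like cells at 0.33.

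Against the neighbouring segment alone, descending contractile genes stood at 0.30, descending collagens at 0.74 and descending HOX genes of fibroblast-like cells at 1.19. Signs changed in SMC-like cells for root paraxial regulators (-0.070), root collagens (0.32), root elastic fibre (0.66), arch proteoglycans (-0.084), descending TGF-beta responsive genes (-0.018) and ascending NF-kappaB genes (0.085). In fibroblast-like cells they changed for descending cardiac regulators (0.080), root matrix proteases (0.30), ascending NF-kappaB genes (0.22) and descending interferon genes (0.017).

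Counting the unnamed cluster as SMC-like gave shares of 14%, 44.8%, 45.2% and 25% from root to descending. In the larger SMC-like cluster, 28 genes were still named and descending collagens stood at 0.47. Signs changed for ascending elastic fibre (0.12), proteoglycans (0.32), immediate early (-0.066) and osteochondrogenic genes (0.12), arch proteoglycans (-0.41) and heat shock genes (0.12), and descending TGF-beta responsive (-0.0088) and NF-kappaB genes (-0.056).

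In the smaller SMC-like cluster, with 8 ascending cells, 9 genes were still named, 20 of the called medians kept their sign and descending contractile genes stood at 0.66. Ascending medians that changed sign were collagens (0.15), elastic fibre (0.96), proteoglycans (0.68), matrix proteases (0.49), TGF-beta responsive (0.21), immediate early (-1.41), osteochondrogenic (1.17), vasoactive (-0.29) and fibroblast markers (1.25). In the arch these were contractile genes (0.78), SMC regulators (0.32), SMC markers (1.24), proteoglycans (-0.70), immediate early (0.36), heat shock (0.30), NF-kappaB (0.085), metallothioneins (0.81), osteochondrogenic (-0.54) and vasoactive genes (0.22). Elsewhere they were neural crest regulators in the root (0.034) and proteoglycans (-0.081), TGF-beta responsive (-0.0098) and oxidative phosphorylation genes (0.15) in the descending aorta.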

Other observations

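Endothelial-like cells, the inner lining of vessels, carried several HOX genes in every segment, the root included. HOXD8 was well above its floor in endothelial-like cells of every segment, at 27.7 CPM in the root (16.1 to 44.4), 46.7 CPM in the ascending aorta (38.4 to 56.3), 49.0 CPM in the arch (33.9 to 68.5) and 43.4 CPM in the descending aorta (19.8 to 82.3). Root SMC-like cells had 1 HOXD8 UMI and descending SMC-like cells stood at 15.3 CPM (5.62 to 33.3, 6 UMIs). HOXB4 was at 42.4 CPM in root and 53.0 CPM in descending endothelial-like cells, and MEOX1, a homeobox gene of paraxial mesoderm, at 47.3 and 53.0 CPM, while pericyte-like cells had 0 MEOX1 UMIs in all segments. HOXB5 had 0 UMIs in root and 10 UMIs in arch endothelial-like cells (14.4 CPM, 6.91 to 26.5). GATA6 ran from 37.8 CPM (24.7 to 55.3) in root to 72.6 CPM (37.5 to 127) in descending pericyte-like cells, with overlapping intervals. The genes named here were chosen after their values were seen, no test was made, and these sums cover 112, 316, 89 and 30 endothelial-like cells from root to descending.

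TBX20, a regulator of heart development, was found in root fibroblast-like cells at 5.83 CPM (4.54 to 7.37, 70 UMIs), with 1 UMI in descending and none in ascending and arch fibroblast-like cells. In the ascending aorta 0 UMIs allow up to 5.19 CPM, which overlaps the root interval. HOXA5, a HOX gene high in descending fibroblast-like cells, stood at 10.2 CPM in descending SMC-like cells (2.78 to 26.1, 4 UMIs) with 0 UMIs in SMC-like cells of the other segments. In descending SMC-like cells the interferon-induced gene IFIT3 reached 74.0 CPM (29 UMIs) against 17.4 to 21.8 CPM elsewhere, whereas ISG15 was lowest there, at 48.5 CPM against 62.8 to 91.4 CPM. Pericyte-like cells lay in clusters that differed by library, with all 130 root cells in 1 cluster and 50 of 84 ascending and 37 of 58 arch cells in the other. An unnamed cluster led by ITLN1, NRG1 and EDN1, with endothelial markers, held 25 arch and 2 descending cells.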
